A study of Rattus norvegicus with 4 samples.

How the data were processed

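The series measured whole rat testis with the Affymetrix Rat Genome U34 array, a short-oligonucleotide array on which each transcript is read by a probe set of matched and mismatched probes. Per the labels, biotinylated cRNA was prepared from 10 micrograms of total RNA. There were 4 deposited samples, 1 per group, each called an array here. They were vitamin A-deficient testis (VAD, the untreated 0 h group) and deficient testis 4, 8 and 24 h after retinol. Whether 1 chip or several stand behind a sample, and how many animals, is not given in the sources used here.

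The values deposited by the authors were linear ratios per probe set, not intensities. GCOS and MAS5, Affymetrix's scanner and signal software, are named in the submitters' processing notes without a version. The step that turned signals into ratios, the reference of the ratios, any pooling of arrays and the scaling between arrays are not given in the sources used here. The deposited ratios showed what they were relative to only in part: the VAD column had a median of 0.995 with an SD of 0.17, and 59.9% of its probe sets lay within 10% of 1, although only 0.386% were exactly 1. The 4, 8 and 24 h columns had medians of 0.934, 0.923 and 0.922 and SDs of 0.418, 0.509 and 0.57. The reference therefore lay close to the VAD sample for most probe sets without being the VAD column itself. Signal levels, detection calls and background were not kept, so a dim transcript cannot be told from a bright one.

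The table held 8799 probe sets, of which 59 were Affymetrix controls. Of the others, 7006 carried 1 gene symbol in the platform annotation, 308 carried several and 1426 were not listed there. Symbols were updated through the Entrez IDs, 6985 of which were found in the RefSeq gene table of assembly GRCr8, used for names and for the genomic span of genes. The probe sets with 1 symbol gave 4736 genes, 1565 with 2 or more probe sets and 3171 with 1. Probe sets with several symbols or none were left out of the comparisons.

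Ratios were put on the log2 scale, a gene's value was the mean over its probe sets, and each change was the difference between 2 arrays. The comparisons were 4, 8 and 24 h against VAD, 8 h against 4 h, and 24 h against 8 h. With 1 array per group no test between groups exists, so no p-value was computed, and genes were counted past a 2-fold change. The design fixed before the data were examined assumed signal levels, with a floor, a filter on level, lists matched on level and the brightest probe set per gene. Ratios carry no level, so these steps were dropped, the mean over probe sets was used, and random lists were drawn from all genes. Choosing the probe set with the highest mean ratio would pick the probe sets that were higher after retinol, so that rule became an alternative.

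Error was taken from pairs of probe sets that read the same gene from different database sequences (1112 genes). The SD of the difference between their changes, divided by the square root of 2, was used as the noise of 1 probe set. It holds probe error, cross-hybridisation and any difference that goes with position along the transcript, and it leaves out the spread between animals. A change that 1 probe set of a pair reads and the other misses also enters it as noise. It was 0.42, 0.51 and 0.57 at 4, 8 and 24 h against VAD and 0.33 and 0.32 between successive retinol arrays. To give a level for counts and overlaps that share the VAD array, 200 tables of unchanged genes were simulated with noise drawn jointly for all 4 arrays from these pairs. Each probe set of a gene had its own draw, also where probe sets come from the same sequence, so noise may be understated for such genes. The procedure was tested on simulated data for the 24 h against VAD step with 4736 genes. Of genes given a 4-fold change, 96% (higher) and 98% (lower) passed the 2-fold threshold. Of genes given a 2-fold change, 38% and 46% passed, and 5.67% of unchanged genes passed as well.

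The genes named are the 10 with the largest positive and the 10 with the largest negative change at each time against VAD and 5 of each between successive times. Retinoid and Kit system genes fixed in advance, up to 4 members of each fixed list and up to 6 genes of each time class with the largest changes were also taken. Only part of the list members and class genes so taken is printed, a choice made after their values were seen. Other list members named in the text were chosen after their values were seen. The level filter of that rule was left out, as the rule provides for values centred per gene. Rarg, Stra8, Cyp26a1, Dhrs3, Lrat and Tgm2 were among the fixed genes but were not named by a probe set with 1 symbol and are not analysed here. The 24 fixed lists covered retinoid metabolism and transport, retinoid receptors and target genes, Sertoli, Leydig, peritubular myoid, macrophage and other leukocyte, and endothelial cells, undifferentiated and differentiating spermatogonia, pachytene spermatocytes, spermatids, blood and epididymis. They also covered the cell cycle, immediate early transcription, heat shock, cholesterol and fatty acid synthesis, extracellular matrix, growth factors, the interferon response, glutathione and oxidative defence, the mitochondrial respiratory chain, ribosomal proteins and housekeeping genes. A list's median change was placed by its percentile among 10000 random lists of the same size drawn from the 4736 genes, which describes these arrays only.

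The alternatives were centring of each array, 1.5-fold and 3-fold thresholds, the list mean in place of the median, and another estimate of the probe set noise. Added after the data were examined were ratios taken against 1, genes with a VAD ratio within 10% of 1, the probe set with the highest mean, genes with 2 or more probe sets, removal of the trend on gene span, lists matched on gene span, all pairs of probe sets for the noise, and scaling of each array on the 9 probe sets of the bacterial hybridisation spike-ins. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.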

Results

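Rats were raised from 20 days of age on a diet without vitamin A and after 9 weeks received retinol, the alcohol form of the vitamin, which tissues oxidise to retinoic acid. Whole testis was profiled before treatment (VAD) and 4, 8 and 24 h after it to follow the transcriptome as the vitamin was restored. In the deficient testis spermatogenesis stops at early germ cells while Sertoli and Leydig cells remain, and retinol restarts it. Each time is 1 deposited sample, called an array here, so no value has a replicate check. None of the differences below was tested between animals. Changes are log2 differences in deposited ratio, each in comparison with the VAD array unless another array is named. The median of all 4736 genes was -0.09 at 4 h, -0.12 at 8 h and -0.12 at 24 h. Scaling the arrays on the bacterial spike-ins added in fixed amounts would move every gene by 0.55, 0.50 and 0.62 at these times. Signs of changes smaller than that hold only for the values as deposited, and gene lists are placed against other genes, which scaling leaves as it is.

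At 4 h after retinol, the nuclear receptor gene Nr0b1 (DAX1, a repressor of steroidogenic transcription) was 1.68 higher, or 3.20-fold. The fatty acid scavenger receptor gene Cd36 was 1.69 higher as the mean of 2 probe sets from the same database sequence, at 1.31 and 2.07. Spermatid genes stood out among the germ cell genes, with the chromatin transition protein gene Tnp2 1.87 higher (3.65-fold). The other genes among the 10 largest positive changes were Gzmn, a granzyme gene (2.08), the G protein subunit gene Gnal (1.88), and the dendritic cell lectin gene Clec9a (1.82). They were followed by Laptm4a of lysosomal membranes (1.80), the natural killer receptor gene Klra22 (1.73), the ganglioside activator gene Gm2a (1.72) and the DNA ligase gene Lig3 (1.67). The forkhead transcription factor gene Foxa2 was at -2.90, or 7.46-fold lower. The bone morphogenetic protein genes Bmp3 (-1.67, with probe sets at -2.18 and -1.16) and Bmp4 (-1.66) were also among the 10 largest negative changes. The rest of these were the vomeronasal receptor gene Vom1r101 (-1.85), the pituitary factor gene Pou1f1 (-1.76), the proteoglycan gene Spock2 (-1.76), the NADPH oxidase gene Nox4 (-1.73), the neurofilament gene Nefm (-1.70), Pdzk1 (-1.66) and the mast cell protease gene Mcpt9 (-1.58).

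The 15 measured spermatid genes had a median change of 0.71 at 4 h, above all 10000 random lists. Smcp of the sperm mitochondrial capsule was 0.80 higher, the hyaluronidase gene Spam1 0.88, the transition protein gene Tnp1 0.75 and the outer dense fibre gene Odf1 0.74. Tnp2 was the 1 member past 2-fold, and 4 of the 15 were lower than VAD. The 14 pachytene spermatocyte genes had a median of 0.24 (percentile 99.8), and the 5 with a VAD ratio within 10% of 1 of 0.13 (percentile 93.0). Pdha2, the testis-specific pyruvate dehydrogenase subunit gene, was at 1.01, Tcp11 at 0.69, Adam2 at 0.66 and Sycp3 of the synaptonemal complex at 0.62. The 5 genes of differentiating spermatogonia and meiotic entry had a median of 0.38 (percentile 98.6). Of these, 3, Sycp1, Sycp2 and Sycp3, are also in the pachytene list. In the VAD column the spermatid list had a median ratio of 1.16, above all random lists, the meiotic entry list of 1.13 (percentile 98.25) and the pachytene list of 1.04 (percentile 90.3). Tnp2 had deposited ratios of 2.09 for VAD, 7.64 at 4 h, 1.99 at 8 h and 1.41 at 24 h. Among the 7 spermatid genes with a VAD ratio within 10% of 1 the median change at 4 h was -0.10 (percentile 51.05), so the 4 h shift was not seen among these. Of the 3 with 2 or more probe sets, Camk4 and Hook1 were at -0.17 and -0.27 and Spam1 at 0.88. Taken against 1 in place of the VAD column the 15 genes were at 0.83 at 4 h (percentile 100).

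Among genes of retinoid handling at 4 h, the retinoic acid binding protein gene Crabp2 was at -0.73 and the retinol dehydrogenase gene Rdh10 at 0.65. The retinol binding protein gene Rbp2 was at 0.56 and the carrier transthyretin gene Ttr at 0.54. The retinal dehydrogenase genes Aldh1a1 and Aldh1a2 were at -0.46 and -0.19 and the retinoic acid hydroxylase gene Cyp26b1 at -0.21. Of the receptors, Rara was at 0.20, Rarb at 0.06, Rxra at -0.06, Rxrb at -0.02 and Rxrg at 0.01, and Crabp1 was at -0.23. None of the 21 genes of retinoid metabolism and transport (median -0.19, percentile 13.3) and none of the 13 receptor and target genes (median -0.02, percentile 75.1) reached 2-fold. The phosphatase gene Dusp1 (1.39, from probe sets at 0.45 to 1.90) was 2-fold higher and Klf6 (-1.07) 2-fold lower among the 39 immediate early genes. Their median was 0.00 (percentile 93.2), with Gadd45a at 0.88 (4 probe sets from -0.12 to 1.44) and Ier3 at 0.71.

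In all, 67 genes were at least 2-fold higher and 59 at least 2-fold lower at 4 h, and after centring of each array the split was 89 to 42. Spike-in scaling gave 446 and 11. Tables of unchanged genes with probe set noise gave means of 47.1 and 49.4 and at most 64 and 73. The noise of a gene with 1 probe set was 0.42. Over the 1112 genes with 2 such probe sets, changes of the pair correlated across genes at r = 0.15 (0.02 after shuffling the partners), so 1 probe set foretold little of its partner's change.

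At 8 h, Nr0b1 was 2.40 higher (5.27-fold), Cd36 2.15 higher and the transferrin receptor gene Tfrc, which takes iron into cells, 2.34 higher. The receptor phosphatase gene Ptprd was 2.76 higher, or 6.78-fold, and Gm2a 2.52. The 10 largest positive changes also took in the semaphorin gene Sema4b (2.33), the ephrin gene Efnb1 (2.23), Klhl14 (2.20), Lig3 (2.19) and the acyl-CoA dehydrogenase gene Acadsb (2.18). Spock2 was at -2.48 and the lymphocyte and epididymal surface glycoprotein gene Cd52 at -2.35. Rpe65, the retinoid isomerase gene of the eye, was at -2.02, the axonemal dynein gene Dnah8 at -1.99, and the tubulin gene Tuba4a at -1.82. Dpysl4 was at -1.73, the sperm surface gene Adam3a at -1.72, Foxa2 at -1.72, Bmp4 at -1.70 and the dehydrogenase gene Hsd17b8 at -1.64.

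Sertoli cell genes at 8 h went both ways around a list median of -0.13 (28 genes, percentile 43.1). The gap junction gene Gja1 was at 1.05, the keratin gene Krt18 at 1.27 and Gdnf, the factor that maintains spermatogonial stem cells, at 1.02, and these were the 3 members past 2-fold. Wt1 followed at 0.94, from 3 probe sets at -0.14 to 1.57. The fatty acid binding protein gene Fabp3 was at -0.77 and the intermediate filament gene Vim at -0.71. The 4 h median was 0.04 (percentile 95.6), with Cmtm2a at 1.41. Among the 11 Sertoli genes with 2 or more probe sets the medians were 0.33, 0.42 and 0.62 at 4, 8 and 24 h, each at percentile 100. The Leydig list (19 genes) had a median of 0.07 at 4 h and 0.00 at 8 h (percentiles 95.5 and 85.7), with Nr5a1 (SF-1, which activates steroidogenic genes) at 0.78 and 1.24. At 8 h Cyp17a1 was at -0.94 and Fdx1 at -0.74, while Cyp11a1 was at -0.22.

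Among retinoid genes at 8 h, Rdh10 was at 1.06 and the fatty acid and retinoic acid binding protein gene Fabp5 at -1.26, the only 2 of the 21 retinoid metabolism genes past 2-fold (list median -0.07, percentile 65.8). Crabp2 was at -0.75, Aldh1a2 at -0.60 and Aldh1a1 at -0.57, with Crabp1 and Cyp26b1 at -0.07. The receptor and target list had a median of 0.09 (13 genes, percentile 92.8), with Kit, the receptor of differentiating spermatogonia, at 0.70, Ppard at 0.59 and Ucp1 at 0.50. The receptors Rara, Rarb, Rxra, Rxrb and Rxrg were at 0.25, -0.05, -0.29, 0.19 and -0.07.

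At 8 h 134 genes were at least 2-fold higher and 89 lower, against means of 91.2 and 93.6 and at most 122 and 116 in tables of unchanged genes. Centring of each array gave 176 and 60, and spike-in scaling 487 and 15. The noise of 1 probe set was 0.51, and the pair correlation across genes was 0.16.

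At 24 h, the steroidogenic genes Cyp11a1 (side-chain cleavage), Cyp17a1 and Fdx1, the electron donor of Cyp11a1, were at -1.95, -1.63 and -1.28, while Nr0b1 was at 2.17 and Nr5a1 at 1.63. The secreted phospholipase gene Pla2g2a was 3.75 higher, a 13.5-fold difference. Kit and its ligand gene Kitlg were 1.01 and 1.09 higher, each as the mean of 2 probe sets (0.76 and 1.25 for Kit, 0.72 and 1.46 for Kitlg). The microtubule regulator gene Dpysl4 was 16.1-fold lower (-4.01) and Spock2 8.68-fold lower (-3.12).

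The other genes of the 24 h positive set were Ptprd (2.92), Gm2a (2.56), the vomeronasal receptor gene Vom2r18 (2.29), and the kinase gene Oxsr1 (2.27), then the adhesion molecule gene Cadm1 (2.16), the neutrophil calcium binding protein gene S100a8 (2.14), Cd36 (2.14) and Sema4b (2.10). Its negative set also held Cd52 (-2.55), the secretoglobin gene Scgb2a1 (-2.24), Tuba4a (-2.01), Hsd17b8 (-1.92), Tesc (-1.79) and the adenylate cyclase gene Adcy4 (-1.72). The GABA receptor gene Gabra4 had a mean of -1.95 from probe sets that disagreed, at -3.95 and 0.06.

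**Figure D1:**
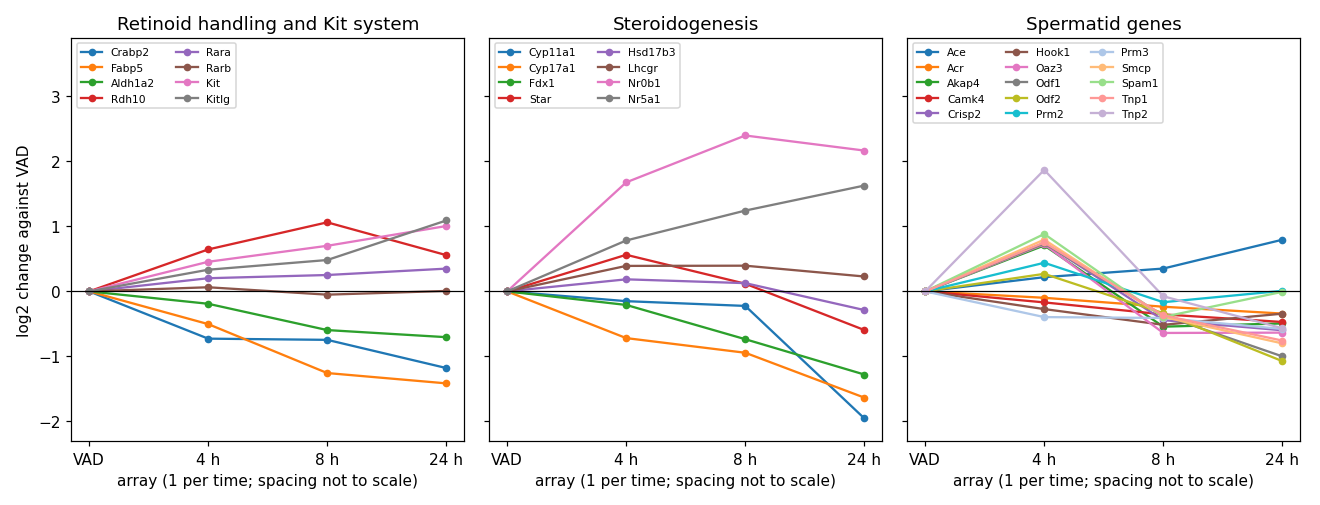
Log2 change from VAD (vertical axis) of 8 genes each of retinoid handling and the Kit system and of steroidogenesis and of the 15 spermatid genes on the VAD, 4, 8 and 24 h arrays (horizontal axis, not to scale). At 24 h Nr0b1 lies at 2.17 and Cyp11a1 at -1.95, and of the spermatid genes 11 lie above VAD at 4 h, 14 below it at 8 h and 13 below it at 24 h, where scaling on the spike-ins turns the spermatid list median at 24 h from -0.57 to 0.05.

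The Leydig list as a whole had a median of -0.12 at 24 h (percentile 49.7), with 2 of 19 genes at least 2-fold higher and 3 lower. Star, which carries cholesterol into mitochondria, was at -0.59, while the luteinising hormone receptor gene Lhcgr was at 0.23 and the testosterone synthesis gene Hsd17b3 at -0.29. The Sertoli list stood at -0.29 (percentile 5.33), with Kitlg, Wt1 (1.03, from 3 probe sets at 0.07 to 1.59) and Gja1 (1.02) at least 2-fold higher and the water channel gene Aqp8 (-1.13) at least 2-fold lower. The matrix list had a median of 0.14 (40 genes, percentile 99.8), and none of the 40 passed 2-fold. The inhibitor gene Timp3 was at 0.85 and the proteoglycan gene Bgn at 0.87 (probe sets at 0.02 and 1.73). The plasminogen activator gene Plat was at 0.79 and the periostin gene Postn at -0.98. The 47 growth factor genes were at 0.04, 0.08 and 0.07 at the 3 times (percentiles 98.6, 99.6 and 98.9). At 24 h Bmp6 was at 1.07 (probe sets at 0.48 and 1.67), Bmp4 at -0.94 and the activin antagonist gene Fst at -0.98. Among members with a VAD ratio within 10% of 1 the growth factor medians were -0.02, -0.02 and -0.06.

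Among retinoid genes at 24 h, Fabp5 (-1.42) and Crabp2 (-1.18) were 2-fold lower and Adh4, an alcohol dehydrogenase gene, 2-fold higher (1.19), around a list median of -0.05 (percentile 70.5). Aldh1a2 was at -0.70, Aldh1a1 at -0.60, Cyp26b1 at -0.14 and Crabp1 at 0.35. Rara was at 0.35 as the mean of 3 probe sets from -0.13 to 0.69, Rarb at 0.01, Rxra at -0.50, Rxrb at 0.40 and Rxrg at -0.30. The receptor and target list had a median of 0.01 (percentile 78.1), with Kit and Crabp2 its members past 2-fold.

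At 24 h 155 genes were at least 2-fold higher and 125 lower, where tables of unchanged genes gave means of 145 and 125, and centring gave 199 and 83. Those tables are built from differences between probe sets on these same arrays, where a change read by 1 of 2 probe sets counts as noise. Counts near their means therefore do not show that no gene changed. Spike-in scaling gave 744 and 13. The noise of 1 probe set was 0.57, and of the 197 pairs in which at least 1 probe set passed 2-fold, both did so in the same direction in 8.

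Ribosomal protein and respiratory chain genes lay below the rest of the transcriptome on all 3 retinol arrays. The 45 ribosomal protein genes had medians of -0.39, -0.61 and -0.56 at 4, 8 and 24 h, and the 54 respiratory chain genes of -0.35, -0.47 and -0.56, below all 10000 random lists each time. Rpl17 was at -1.15, -1.26 and -1.02, Rpl30 at -1.14, -1.25 and -0.94, and Rpl22 at -0.59, -0.95 and -0.82, while the ribosomal protein-like gene Rplp1l3 was at 1.04, 1.03 and 1.75. Of the complex I genes, Ndufb2 was at -0.76, -0.99 and -1.11 and Ndufb9 at -0.73, -0.82 and -1.13, Uqcr11 of complex III was at -0.55, -0.78 and -0.83, and Ndufs1 at 0.65, 0.98 and 0.92. Few members passed 2-fold: 2, 3 and 2 members of the ribosomal list were lower by that much, and 0, 0 and 2 respiratory chain genes. The ribosomal list was taken by the symbol prefixes Rpl and Rps. It holds the pseudogene symbol Rps4x-ps9 (-0.84, -1.04 and -1.08), which is among those counted at 8 h and 24 h. At 24 h 42 of 45 and 50 of 54 lay below VAD.

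The sign of these medians, though not their place below other genes, depends on scaling. The 9 hybridisation spike-in probe sets had median changes of -0.55, -0.58 and -0.71, and all 9 were lower at each time. Scaling the arrays on them would turn the ribosomal medians to 0.16, -0.11 and 0.06 and the respiratory chain medians to 0.20, 0.03 and 0.06. The control probe sets along the actin, GAPDH and hexokinase transcripts moved apart at the same times. The change at the 5' end exceeded that at the 3' end by 0.71 at 4 h, 1.09 at 8 h and 1.01 at 24 h as the mean of the 3 transcripts. For beta-actin the 5' probe set was at 1.11, 1.29 and 1.52 and the 3' probe set at 0.06, 0.01 and 0.22. The 5' probe set of GAPDH stayed short of 2-fold (0.57, 0.63 and 0.59). That of hexokinase passed it at 8 h and 24 h (0.85, 1.33 and 1.36). Where probe sets lie along transcripts was not examined for genes, so any change against VAD may hold such a difference.

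**Figure D2:**
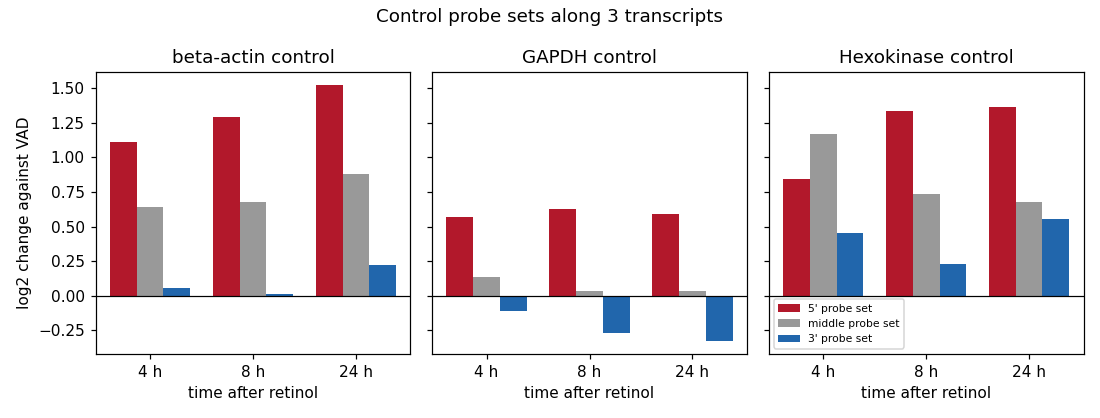
Log2 change from VAD (vertical axis, bars from 0) of the 5', middle and 3' control probe sets of beta-actin, GAPDH and hexokinase at 4, 8 and 24 h (horizontal axis), 1 array each. The 5' bar exceeds the 3' bar for each transcript and time, by 1.30 for beta-actin at 24 h, a difference that scaling of arrays leaves unchanged.

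Between 4 h and 8 h, spermatid genes made up the clearest group. The list had a median difference of -1.11 between the 8 h and 4 h arrays, below all random lists, with 8 of 15 genes at least 2-fold lower at 8 h. With the probe set of the highest mean the median was -0.67, and among the 3 genes with 2 or more probe sets -0.24 (percentile 4.9). The pachytene list had a median of -0.43, also below all random lists, with 3 of 14 genes past 2-fold. Among its 5 genes with a VAD ratio within 10% of 1 the median was -0.09 (percentile 30.8). Tnp2 was at -1.94, the testis fatty acid binding protein gene Fabp9 at -1.83, Adam3a at -1.82 and Cmtm2a at -1.75. The receptor gene Mas1 at -1.61 completed the 5 largest negative differences. On the positive side were the kininogen gene Kng2 (2.16), Ptprd (1.58), the nicotinic receptor gene Chrna5 (1.42), the lipase gene Pnliprp2 (1.35) and the bile acid synthesis gene Cyp7a1 (1.65, from probe sets at 0.46 and 2.84). The meiotic entry list was at -0.42 (5 genes, percentile 0.305), and cholesterol and fatty acid synthesis at -0.19 (21 genes, percentile 0.46, or 3.6 with the probe set of the highest mean). Ribosomal proteins were at -0.18 (percentile 0.01) and the receptor and target list at 0.16 (percentile 98.5). Counts were 34 genes at least 2-fold higher and 44 lower, against means of 20.4 and 20.2 and at most 32 and 34 in tables of unchanged genes. Among the 7 spermatid genes with a VAD ratio within 10% of 1 the median was -0.18 (percentile 4.45).

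Between 8 h and 24 h, Cyp11a1 was at -1.73, with Dpysl4 (-2.29), the interferon-induced gene Mx2 (-1.86), the hyaluronan synthase gene Has2 (-1.83) and Amelx (-1.80, from probe sets at -2.88 and -0.72) as the other large negative differences. Vom2r18 (1.65), Pla2g2a (1.63), Acsm3 (1.53), Dnah8 (1.40) and the calcium binding protein gene Calb1 (1.37) were the 5 largest positive ones. The 5 meiotic entry genes had a median of 0.30 (percentile 99.1) and the respiratory chain of -0.07 (percentile 2.2, or a median of 0.05 after spike-in scaling). The Leydig list had a median of -0.12 (percentile 2.17), the receptor and target list of -0.21 (percentile 0.35), heat shock and protein folding of -0.11 (24 genes, percentile 1.56) and the matrix list of 0.11 (percentile 99.6). Spike-in scaling, which shifts all genes by 0.12 here, would bring the Leydig and heat shock medians to 0.00 and 0.01. With the probe set of the highest mean they were at -0.01 and -0.05 (percentiles 41.05 and 16.4), inside the middle 95% of random lists. Among Leydig genes with a VAD ratio within 10% of 1 the median was -0.12 (percentile 4.6). There were 24 genes at least 2-fold higher and 31 lower, where unchanged genes gave means of 28.3 and 25.7 and at most 48 and 47. Spike-in scaling gave 45 and 20.

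Over the time course, 36 genes were at least 2-fold higher at all 3 times, among them Pla2g2a (1.18, 2.13 and 3.75), Ptprd, Gm2a, Nr0b1, Cd36 and Oxsr1. Lower at all 3 were 19, among them Spock2, Foxa2, Cd52, Tuba4a, Hsd17b8 and Bmp3 (at 24 h from probe sets at -2.52 and -0.20). Spike-in scaling gave 249 and 1, and centring 47 and 10. By the same 2-fold cut the 5' control probe set of beta-actin, but not its 3' one, would be higher at all 3 times. Genes higher at 4 h only numbered 17, with Tnp2, Clec9a, Birc2, Rnd3 and Cmtm2a among them. Lower at 4 h only were 21, among them Pold1 and the regenerating islet genes Reg3a and Reg3b. At 8 h and 24 h but not 4 h 61 were higher, including Acadsb, the zinc transporter gene Slc30a1 and Kng2, and 22 lower, including Dpysl4, the angiopoietin gene Angpt2 and Fabp5. At 8 h only 27 were higher (St3gal3, Pnliprp2 and Krt18 among them) and 37 lower (Dnah8, Adam3a and the BMP antagonist gene Nog among them). At 24 h only 54 were higher, including S100a8 (2.14), its partner S100a9 (1.52) and Fabp2 (1.58), and 76 lower, including Cyp11a1, Tesc, Adcy4 and Cyp17a1. These classes rest on the 2-fold cut, and some members lay just short of it at another time. At 8 h Adcy4 was at -0.97, Cyp17a1 at -0.94 and S100a8 at 0.96, while Cyp11a1 was at -0.22 and Tesc at -0.33. Rnd3 was at 0.94 at 24 h and Pold1 at -0.88 at 8 h. No gene passed 2-fold in both directions. Tables of unchanged genes gave means of 17.7 higher and 19.9 lower at 4 h only, 53.7 and 45.5 at 8 h and 24 h, 14.0 and 18.8 at 8 h only and 64.4 and 55.4 at 24 h only. Lower at 8 h only (37) was the 1 class of these past the highest such table (29). The 3 comparisons share the VAD array, and tables of unchanged genes gave on average 20.8 genes higher (at most 32) and 23.6 lower at all 3 times. Of the 8 h and 24 h calls, 97 higher and 41 lower were shared. Independent lists would share 4.39 and 2.35, and tables of unchanged genes 74.5 and 69.1, so the 41 shared lower calls lay below that level. The simulated noise was drawn jointly over the 4 arrays, so it holds what the 8 h and 24 h arrays share as well as the VAD array. The deposited 8 h and 24 h ratios, without the VAD column, correlated at r = 0.83 over all probe sets. The part that comes from the VAD array was not separated. Changes at 8 h and 24 h correlated across genes at r = 0.82, where the noise of single probe sets, with the VAD array shared, gave 0.84.

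**Figure D3:**
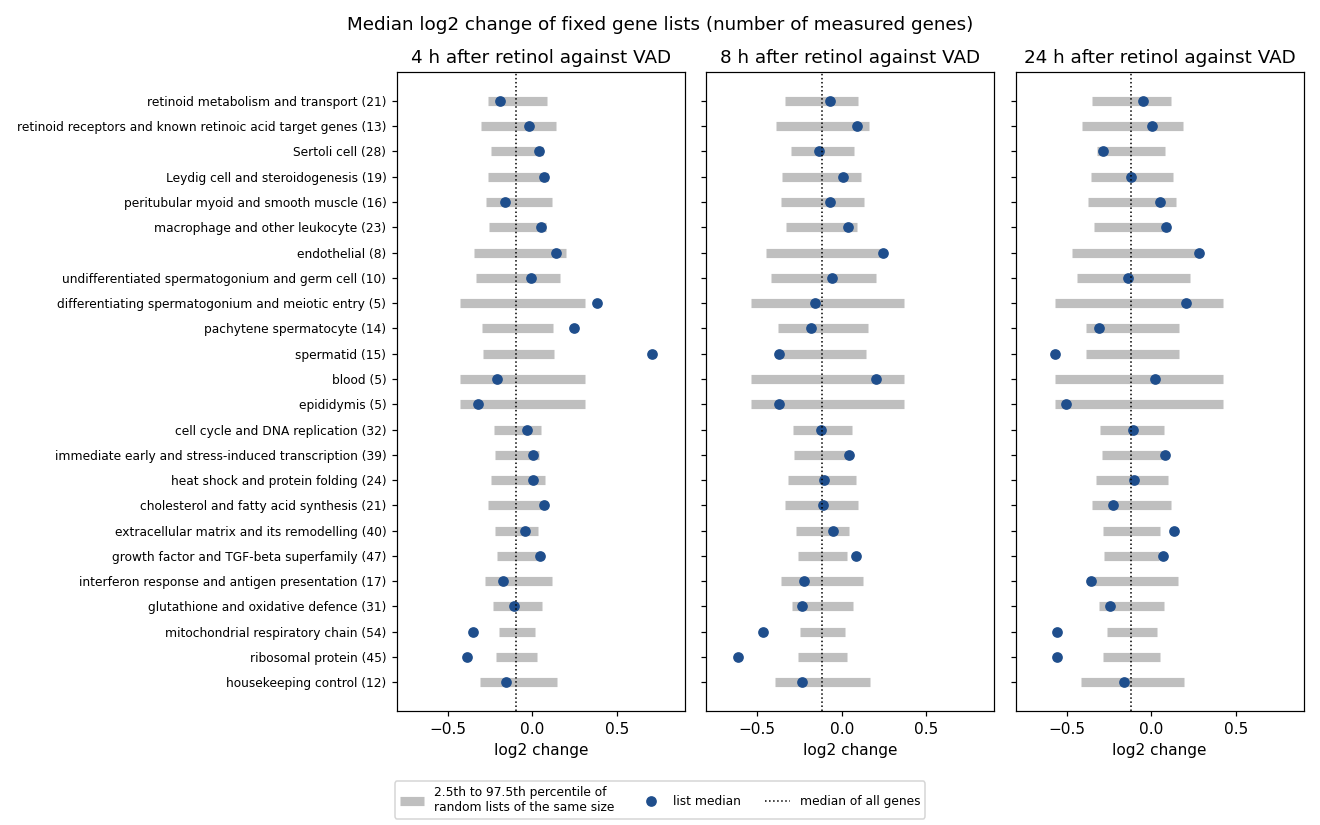
Median log2 change from VAD (horizontal axis) of the 24 fixed gene lists (vertical axis, measured genes in parentheses) at 4, 8 and 24 h. Points are list medians, bars the middle 95% of 10000 random lists of the same size, and the dotted line the median of all genes. Ribosomal protein (-0.56 at 24 h) and respiratory chain lists lie below their bars at each time and the spermatid list above its bar at 4 h (0.71) and below it at 24 h (-0.57, where spike-in scaling turns the ribosomal and spermatid medians to 0.06 and 0.05).

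Of the other cell types, the 23 macrophage and leukocyte genes had medians of 0.05, 0.03 and 0.08 (percentiles 95.2, 92.1 and 96.0). With the probe set of the highest mean they were at 0.25, 0.31 and 0.39 (percentiles 99.3, 100 and 99.9), and against 1 at -0.03, 0.03 and -0.03. At 24 h the chemokine gene Ccl3 was at 1.77, Cd4 at 1.32, C1qc at 1.05 and the class II gene RT1-Db1 at -0.84. The 8 endothelial genes were at 0.14, 0.24 and 0.28 (percentiles 94.7, 98.0 and 97.8), with Kdr at -1.35 and Pecam1 at 0.65 at 24 h. Among members with a VAD ratio within 10% of 1 the endothelial medians at 8 h and 24 h were 0.08 and -0.02 (percentiles 89.8 and 73.5). The 16 peritubular myoid genes were at -0.16, -0.07 and 0.05 (percentiles 24.1, 65.0 and 89.6), with the caldesmon gene Cald1 at 1.62, 1.79 and 1.82. Undifferentiated spermatogonium genes were at -0.01, -0.06 and -0.14 (10 genes, percentiles 76.3, 65.5 and 45.6), with Uchl1 at 0.77 and Ret at -0.45 at 24 h. Spermatid genes at 8 h and 24 h had medians of -0.37 and -0.57 (percentiles 2.77 and 0.07), with Odf2 at -1.07, Smcp at -0.80 and Ace at 0.79 at 24 h and Odf1 2-fold lower. Taken against 1, spermatid medians were -0.17 and -0.29 (percentiles 35.4 and 12.7), inside the middle 95% of random lists. Pachytene genes had medians of -0.18 and -0.31 (percentiles 31.3 and 9.12). The meiotic entry genes stood at -0.16 and 0.21 at those times (percentiles 42.0 and 90.9). Blood genes were at -0.21, 0.20 and 0.02 (5 genes, percentiles 24.8, 91.6 and 71.6). Epididymis genes were at -0.32, -0.37 and -0.50 (5 genes, percentiles 8.77, 12.5 and 5.02), with Adam7 at -0.95 and Defb1 at -0.83 at 24 h.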

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

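Of the tests in this part, that on the control transcripts was chosen after the result was seen. That on gene span was chosen before its own result was seen, though after the data were examined.

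The control probe sets lie outside the gene comparisons, and their 5' ends differed from their 3' ends between the arrays. The 5' minus 3' change from VAD to 24 h was 1.3 for beta-actin, 0.914 for GAPDH and 0.804 for hexokinase.

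Ribosomal protein and respiratory chain genes lay low on all 3 retinol arrays relative to other genes. One scaling factor per array moves all genes alike and leaves such a place as it is, so scaling was not put to a test. The tables argue against a bias that follows gene span, whose correlation with change across genes was at least 0.0852, since both lists stayed below the 2.5th percentile of random lists matched on span at each time (transcript length was not tested). Of the explanations put to a test, lower RNA integrity or a stronger 3' bias of the VAD array stays open. The 5' minus 3' difference was at least 0.708 at each time, and such a bias may raise short, intact transcripts on that array. A dependence on signal level could not be tested, since the ratios hold no level. A response to retinol itself is untested, because VAD is 1 deposited sample and its quality and its condition go together.

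Among the 1734 probe sets that no single gene names, 14 were at least 2-fold higher than VAD at all 3 times, or 0.807%, beside 0.76% of named genes, and 14 were lower, or 0.807%, beside 0.40% of named genes. The units differ, since 1565 of the 4736 named genes are means over 2 or more probe sets. Of those 1565, 6 were higher and 2 lower at all 3 times.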

How the results depend on the processing

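Ratios against 1, VAD ratios within 10% of 1, the probe set with the highest mean, genes with 2 or more probe sets, gene span, spike-in scaling and the pairs behind the noise were chosen after the data were examined. The cause of the changes below was not tested unless the setting's own construction gives it. Counts run higher then lower at 4 h, 8 h, 24 h, between 4 h and 8 h, between 8 h and 24 h, and at all 3 times. A 1.5-fold threshold gave 292 and 314, 404 and 584, 426 and 666, 171 and 161, 146 and 149, and 179 and 142. A 3-fold threshold gave 14 and 9, 25 and 11, 31 and 14, 2 and 5, 2 and 5, and 7 and 1. Genes with a VAD ratio within 10% of 1, which are fewer, gave 21 and 24, 42 and 40, 44 and 53, 12 and 12, 13 and 10, and 10 and 8. Genes with 2 or more probe sets, 1565 in number, gave 9 and 4, 23 and 8, 30 and 19, 4 and 4, 3 and 6, and 6 and 2. Spike-in scaling gave 446 and 11, 487 and 15, and 744 and 13 against VAD, 45 and 20 between 8 h and 24 h, and 249 and 1 at all 3 times. The probe set with the highest mean, which prefers probe sets that were higher, gave 132, 239 and 278 higher against VAD, 39 between 8 h and 24 h and 73 at all 3 times. Against a ratio of 1 there were 103 and 91 at 4 h and 38 lower at all 3 times. Centring gave 83 lower at 24 h and 10 lower at all 3 times. The remaining counts stayed within 1.5 times.

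For lists outside the middle 95% of random lists, sign changes of the median came from 4 settings. With VAD ratios within 10% of 1, the spermatid list at 4 h was at -0.0986, the endothelial list at 24 h at -0.0208 and the growth factor list at -0.022, -0.0228 and -0.0616 at 4, 8 and 24 h. With 2 or more probe sets the spermatid list at 4 h was at -0.169, and against 1 the immediate early list at 24 h was at -0.0425. Spike-in scaling, which shifts all genes together, reversed ribosomal proteins at 4 h (0.161) and 24 h (0.0645), the respiratory chain at 4 h (0.199), 8 h (0.0329) and 24 h (0.0628) and from 8 h to 24 h (0.0531). It also reversed spermatid genes at 24 h (0.0542) and, from 8 h to 24 h, the Leydig list (0.00331) and heat shock (0.0115). Among named genes past 2-fold, Gabra4 at 24 h turned to 0.0552 with its highest probe set. Counting all lists, 156 of 882 alternative list medians changed sign, 140 of them from lists inside the middle 95%. Spike-in scaling gave 58 of these, the highest probe set 19, 2 or more probe sets 18, VAD ratios within 10% of 1 17, centring 15, the list mean 12, ratios against 1 10 and gene span 7. Of 627 alternative values of named genes 28 changed sign. The alternative lay within 1 SD of random list medians for 615 list medians and within 1 SD of probe set noise for 527 gene values. The median absolute deviation gave a probe set noise of 0.39, 0.46 and 0.52 at 4, 8 and 24 h, 0.24 between 4 h and 8 h and 0.20 between 8 h and 24 h. Over 522 placements under the settings other than scaling and the list mean, 36 of 129 list medians outside the middle 95% of random lists came to lie inside it, and 35 inside it came to lie outside. Removing the trend on gene span left all list medians and gene values within 1 SD and all counts within 1.5 times. Under that setting 4 of 30 list medians outside the middle 95% came to lie inside it, and 3 inside it came to lie outside.

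Not run, because ratios hold no level, were floors at the 10th and 40th percentile, log2 of the value plus the 20th percentile, level filters at the 25th and 75th percentile and list members above the 25th percentile. Quantile normalization was not run either, since the VAD column's narrow spread belongs to the ratio scale. No filter on level, the mean over probe sets and random lists not matched on level became the reported setting. No paired analysis was possible because each group has 1 array, and no array could be left out in turn. Signal over background is unknown for all genes.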

Other observations

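Of the tests in this part, those on the control transcripts and on Leydig cell genes were chosen after the result was seen, and that on the second germ cell list before it.

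Several stress, metabolic and immune groups have not been described at 24 h. Among 31 genes of glutathione and oxidative defence (medians -0.11, -0.24 and -0.24 at 4, 8 and 24 h, percentiles 42.8, 9.03 and 10.2), 2 passed 2-fold at 24 h. The extracellular superoxide dismutase gene Sod3 was at 1.41 and Gclc, the rate-limiting enzyme gene of glutathione synthesis, at 1.11. Mitochondrial chaperonin genes lay at the low end of the heat shock list, with Hspe1 at -1.38 and Hspd1 at -1.16 at 24 h (24 genes, medians 0.00, -0.11 and -0.10, percentiles 88.1, 53.7 and 54.7). The 17 interferon and antigen presentation genes had medians of -0.17, -0.22 and -0.36 (percentiles 21.1, 19.2 and 3.13), with Mx2 at -1.11, Stat2 at -0.86, Psmb9 at -0.64 and the receptor gene Ifngr1 at 1.09 at 24 h. Cholesterol and fatty acid synthesis genes were at 0.07, -0.11 and -0.23 (21 genes, percentiles 96.2, 53.3 and 17.1), and at 0.24, 0.36 and 0.20 with the probe set of the highest mean (percentiles 99.7, 100 and 96.7). At 24 h the carboxylase gene Acaca was at 1.22, Acat2 at -0.99 and Mvd at -0.97. The immediate early list had medians of 0.05 and 0.08 at 8 h and 24 h (percentiles 97.4 and 98.5), with Gadd45a 2.53-fold and 2.14-fold higher and Dusp1 at 1.30 and 1.14. Probe sets of Dusp1 ran from 0.09 to 1.92 and from -0.01 to 1.96, and those of Gadd45a at 24 h from 0.32 to 1.64. Against 1 the list was at -0.04 at 24 h (percentile 80.95).

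The 32 cell cycle genes stood near the median of all genes at each time (-0.03, -0.12 and -0.11, percentiles 81.1, 48.1 and 54.8). Pold1 was at -1.37 at 4 h and Pcna at -0.61 and Stmn1 at -0.74 at 24 h. Housekeeping genes were at -0.15, -0.24 and -0.16 (12 genes, percentiles 28.8, 19.3 and 38.2), with Polr2a at 1.07 and Pgk1 at -0.95 at 24 h, and their signs, unlike their places, depend on scaling. The matrix list was at -0.04 and -0.05 at 4 h and 8 h (percentiles 79.1 and 79.4), with Serpine2 at -0.84 at 4 h and 0.57 at 24 h.

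In the VAD column itself, 6 of the 24 lists lay outside the middle 95% of random lists. Median VAD ratios were 1.16 for spermatid, 1.05 for ribosomal protein, 1.04 for respiratory chain and 1.19 for epididymis genes (percentiles 100, 99.7, 99.7 and 99.8), 1.13 for meiotic entry genes (percentile 98.25) and 0.909 for undifferentiated spermatogonium genes (percentile 1.34). Taken against 1 in place of the VAD column, ribosomal proteins were at -0.29, -0.49 and -0.46 and the respiratory chain at -0.23, -0.35 and -0.49.

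Spermatid genes were higher on the 4 h array than on the 8 h and 24 h arrays, whole tissue in which vitamin A deficiency depletes late germ cells. A second list of 16 spermatocyte and spermatid genes, sharing none with the fixed lists, had a median at percentile 99.7 for the change from 8 h to 4 h, but at -0.22 from 4 h to 8 h it was much smaller than the -1.11 of the spermatid list, with 13 genes below the median of all genes, 2 of them past 1.5-fold (Adam5 at -1.12 and Atp1a4 at -1.06), and Pde1c at 0.43. More late germ cells in the tissue behind the 4 h array, such as a testis less depleted before treatment, may contribute to the pattern, as a hypothesis. The second list does not show a shift of that size. Whether its genes are expressed only in late germ cells was not checked, so its smaller median does not decide this. RNA integrity cannot be told apart from more late germ cells. The mean 5' minus 3' difference of the control transcripts between these arrays, 0.384, lay between the bounds set for and against RNA integrity. Regulation by retinol within hours is untested, with 1 array per time.

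Cyp11a1, Cyp17a1, Fdx1 and Star were lower at 24 h than at 8 h, with a median of -0.70. A difference in RNA integrity between these arrays is not excluded: the mean 5' minus 3' difference of the control transcripts was -0.0847, under the bound of 0.2 set against it but by less than the SD of 0.19 over the transcripts, with hexokinase at -0.30 beside 0.03 for beta-actin and 0.02 for GAPDH. A smaller share of Leydig cells may contribute: Lhcgr, Hsd17b3, Hsd11b1 and Prlr had a median of -0.14, or 0.56 above the other 4 genes. With a probe set noise of 0.28 for that difference it lay under the bound of 3 times the noise, 0.84, and with noise from the median absolute deviation just above the bound, 0.53, so a smaller share and a change within the cells cannot be told apart. Regulation of these genes after retinol, beside Nr0b1 at 2.17 at 24 h, is left open and untested.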
